A study of Homo sapiens with 20 samples.

How the data were processed

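The series holds single-nucleus ATAC-seq libraries from 3 spinal cord segments of 1 donor. Per the labels' protocols, nuclei were isolated by homogenizing the tissue and centrifuging it on a gradient, and libraries were made with a BioRad ddSEQ single-cell ATAC kit, in which beads tag the nuclei in droplets. Per the submitters' processing notes, MACS2 2.2.7.1, a peak caller, and the genome build GRCh38 were used. Their roles, the aligner, the way features were defined and counted and any filter on barcodes are not given in the sources used here. The deposited values are whole-number counts per feature and barcode, 1 matrix per segment, with 431482 features in each and 18681 to 364797 barcodes. Of the entries, 89.3% to 93.1% equal 1. Barcode names carry the library name and a number of bead tags, which served to assign each barcode to a library. The Lumbar matrix also holds 55688 barcodes of 1 library that the labels used here do not list; they were not analysed.

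The features have no names or coordinates in the files used here and no genome was used, so no gene, chromosome or cell type is named, and the tests planned for genes (HOX genes, gene lists, marker genes, a narrower gene window) were not run. The tests planned per gene were run per feature. For lack of names, only 2 features each way are given per comparison, those with the largest log2 ratios and at least 50 counts in the higher segment, by the rule set before the data were examined. The further limits of that rule for genes, an adjusted p under 0.05 and all libraries of 1 segment on 1 side, were applied to features too. Chromosomes could not be told apart by name, so the planned limit to autosomes was replaced by leaving the last 20000 rows of the feature list out of every step, which may not amount to the same. Towards 20 shared end rows in the list, 18 to 20 libraries hold no count over runs of 1 to 3284 rows, and the length of the run differs by library (1796 to 26562 rows per library in all). Such rows, 37048 in all, and the 979 rows after the last shared end were left out, after this had been seen. In 380 of 380 windows of 1000 rows the profile of a library lined up best with that of Lumbar library 2 with no shift, so rows stand for the same features in all libraries. The 373455 rows used hold 91.3% of the counts. The cause of the empty runs was not tested.

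A barcode with at least 1000 counts was kept as a nucleus. Nuclei were clustered with Scanpy 1.11.5 on Python 3.11.15 (scikit-learn 1.9.0, SciPy 1.17.1, igraph 0.11.9): term frequency-inverse document frequency of 44234 features seen in at least 1% of nuclei, 30 components of a singular value decomposition (none correlated with log depth above 0.75), 15 neighbours and Leiden clusters at resolution 0.6. Clusters of at least 100 nuclei with at most 90% from 1 library were joined into families. The rule was average linkage with a mean correlation of profiles above 0.5, set after the clusters had been seen. A profile was log2 CPM (counts scaled to a common total), after adding 5, over features with 2000 counts or more. Each feature's mean over these clusters was subtracted first. The correlations are therefore between deviations from the average cluster. Doublets were not called, since the planned caller needs genes; leaving out the 5% deepest nuclei of each segment was the alternative. The share of each family was compared between segments over libraries with an exact two-sided permutation test of the difference of means (3003 permutations for 8 against 6 libraries, 924 for 6 against 6), with Benjamini-Hochberg adjustment over 21 tests. The p is the smaller one-sided p times 2. The share of permutations with as large an absolute difference was used at first; the change was made after the results had been seen, and none of the 21 calls differs (14 pass either way).

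Counts were summed per library over nuclei, over all families and within the 6 families with at least 100 nuclei in every segment. Features with at least 200 counts over all libraries entered edgeR 4.0.16 on R 4.3.3 (TMM factors, quasi-likelihood fit of all 3 segments together, quasi-likelihood F test, Benjamini-Hochberg at 0.05), with no covariate. A standard error is the log2 ratio over the square root of F. Whether a difference differs between families A and B was tested with an interaction term and a term per library. In counts simulated from these libraries with 200 of 20000 features changed, edgeR recovered for Thoracic and Cervical 28.4% of 1.5-fold, 67.2% of 2-fold and 92.4% of 3-fold changes, for Lumbar and Cervical 31.3%, 71.6% and 95.5%, and for Lumbar and Thoracic 25.4%, 77.6% and 95.5%. Of the calls, 6.72%, 6.38% and 7.04% were false. Apart from the changed features all simulated libraries had the same mean profile, with no shift over abundance. These rates therefore need not hold for the real calls, which were far more numerous. Libraries of a segment differed by more than counting noise: chi-square per feature between pairs was 1.18 to 1.65 in Cervical, 1.30 to 3.99 in Thoracic and 1.26 to 1.90 in Lumbar libraries, and none was counted as a repeat.

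The alternatives planned before the data were examined were nuclei of at least 500 or 2000 counts, no feature minimum, DESeq2 size factors, DESeq2 1.42.0, the library number as a block, binarized counts, equal family shares, no 5% deepest nuclei, Leiden resolutions 0.3 and 1.2, and nuclei thinned to 1000 counts. Alternatives added after seeing the data were a lowess offset over abundance per library (span 0.3) and fits of only the compared segments. Others left out each library, Thoracic libraries 2, 3, 6 and 7 or Lumbar library 2, or used each kind of file alone. The empty rows were put back, clusters were made without called features, and family C and the unassigned clusters were left out together. Families were joined at correlations of 0.4 and 0.6, and shared calls of families were taken from other libraries. Libraries were divided into kinds of file by whether the median barcode had under 1000 counts (9 libraries) or not (11 libraries). Other splits of the libraries into groups of the same sizes were drawn 100 times with a fixed seed on 10000 features, or up to 5000 within families; fewer had been drawn at first, and the larger number moved Lumbar against Cervical in family F past the limit of 5%. Figures were drawn with Matplotlib 3.10.9.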

Results

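Chromatin accessibility was measured in single nuclei from a cervical, a thoracic and a lumbar segment of the spinal cord of 1 tissue donor (segments C6, T4 and L4). The assay, snATAC-seq, cuts open chromatin with a transposase and counts the cuts per genomic feature in each barcoded nucleus. The design asks which nuclei and which features differ between the levels of the cord. There were 6 Cervical, 8 Thoracic and 6 Lumbar libraries. All 20 libraries came from the same donor, so every p-value here measures only the spread between libraries, which may be technical. Features have no names or positions in the files used here, so they are given by row number, and nuclei are described by numbered clusters without cell type names.

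The libraries held 41245 nuclei with at least 1000 counts. Cervical libraries gave 14092 nuclei with a median of 2465 counts, Thoracic libraries 11450 nuclei with a median of 3002.5, and Lumbar libraries 15703 nuclei with a median of 2065. Counts in nuclei ranged from 4673075 to 10568142 per Cervical library, from 3475986 to 8337476 per Thoracic library and from 4144249 to 11350876 per Lumbar library. The top 1% of features took 21.5% ± 1.02 (SD, n = 6) of the counts of a Cervical library, 27.3% ± 2.38 (SD, n = 8) of a Thoracic and 18.6% ± 0.884 (SD, n = 6) of a Lumbar library. The files were of 2 kinds. In all 6 Lumbar libraries and in Thoracic libraries 2, 3 and 7 most barcodes were under 1000 counts, and nuclei held 37.3% to 61.4% of the counts. In the 6 Cervical and the other 5 Thoracic libraries nuclei held 92.8% to 98.9%. Lumbar and Cervical libraries therefore differed in kind throughout, and their comparison has no value within 1 kind.

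The nuclei fell into 18 clusters, of which 13 joined into 7 families. Joining was by the correlation of their accessibility profiles, taken as deviations from the mean over clusters. Family A (clusters 1, 2, 9 and 10) held 17230 nuclei and family B (clusters 3, 7, 8 and 12) 11440. Families C to G were 1 cluster each. Families C and F stayed apart only narrowly, with a correlation of 0.4987 between clusters 4 and 11, just under the limit of 0.5. Family C (cluster 4) had 4136 nuclei with a median of 1481 counts, and the top 1% of features took only 5.85% of its counts, against 10.01% in family F and 23.5% to 26.0% in families A, B, D, E and G. Family D (cluster 5) had 3579 nuclei with a median of 4971 counts. Family E (cluster 6) had 2736 nuclei, family F (cluster 11) 1395 and family G (cluster 13) 443. Family G had the highest median, 5511 counts. Among features with at least 50 counts in it, only 29 were at 2-fold over other clusters and 0 at 4-fold. Doublets were not called, so whether family G holds doublets was not tested. Clusters 14 to 18 stayed outside the families, as each had fewer than 100 nuclei.

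**Figure D1:**
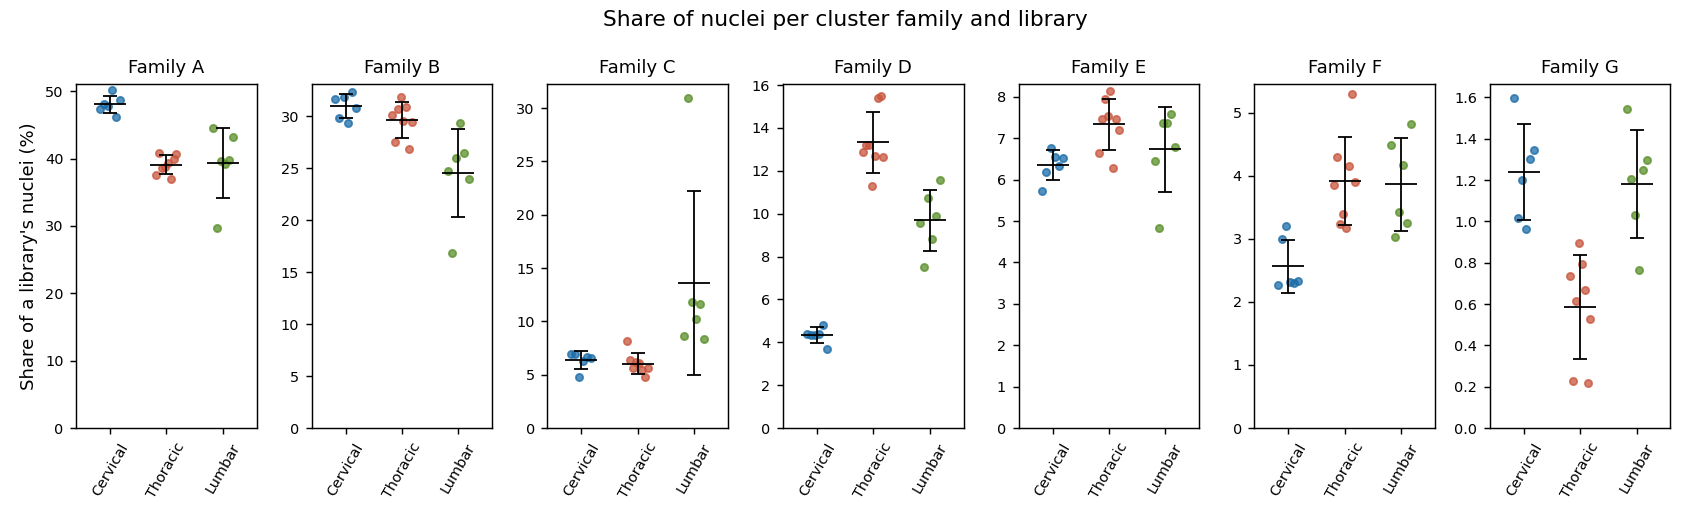
Share of each library's nuclei (percent, y axis) in families A to G, by segment. Points are libraries (6 Cervical, 8 Thoracic, 6 Lumbar), the black line is the mean and the bar 1 SD; family D lies between 11.3% and 15.5% in Thoracic and between 3.68% and 4.83% in Cervical libraries.

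Family D had the largest ratio of Thoracic to Cervical share. In percentage points family A (-8.95) differed about as much as family D (9.02). Family D made up 13.3% ± 1.42 (SD, n = 8) of the nuclei of a Thoracic library and 4.32% ± 0.369 (SD, n = 6) of a Cervical library, a ratio of 3.09, and all 8 Thoracic libraries lay above all 6 Cervical ones. Family F also took a larger share in Thoracic libraries, 3.91% ± 0.700 against 2.57% ± 0.419, and so did family E, 7.34% ± 0.622 against 6.35% ± 0.364. Family A took a smaller share, 39.1% ± 1.38 against 48.04% ± 1.31, and so did family G, 0.585% ± 0.2502 against 1.24% ± 0.233. In the exact two-sided permutation test the adjusted p was 0.0035 for families A, D and G, 0.0041 for F and 0.011 for E (n = 8 and 6; Benjamini-Hochberg over 21 tests); an unadjusted p of 0.000666 is the smallest the permutations can give. Families B (29.6% ± 1.71 against 31.0% ± 1.19, adjusted p = 0.17) and C (6.05% ± 1.00 against 6.37% ± 0.810, adjusted p = 0.62) did not pass this exact test. Among libraries with few low-count barcodes, family D held 12.97% ± 1.49 (SD, n = 5) of Thoracic and 4.32% ± 0.369 (SD, n = 6) of Cervical nuclei. The call for family A ended with coarser clusters, where the difference was -1.22 percentage points, and that for family E among libraries with few low-count barcodes, where it was 0.818. With nuclei of at least 2000 counts the calls for E and F ended (0.897 and 0.263 points) and the difference for B turned to 1.84. Family C passed as lower in Thoracic libraries with coarser clusters (-7.95 points), with nuclei of at least 2000 counts (-5.19) and with nuclei thinned to 1000 counts (-2.16). Clusters 3, 7 and 12 of family B, without cluster 8, took a larger share in Thoracic libraries (3.04 points).

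Accessibility differed between Thoracic and Cervical libraries at 47418 of 110034 tested features, 23387 of them higher and 24031 lower in Thoracic (edgeR, adjusted p under 0.05). This near balance turned under other settings, with 24371 higher and 22806 lower under DESeq2 size factors, 23529 and 21455 in DESeq2 itself and 42418 and 32157 with no minimum of counts. At 2-fold or more, 2670 features were higher and 8103 lower. Among the features whose 8 Thoracic libraries all lay on 1 side of the 6 Cervical ones, the largest rises were at feature 229703, with a log2 ratio of 2.40 ± 0.28 (SE, edgeR adjusted p = 6.39e-09), and feature 227589, with 2.35 ± 0.38 (adjusted p = 2.85e-06). Feature 229703 had 6.50 ± 2.86 CPM (normalised counts, scaled to a common library total) in Thoracic (SD, n = 8) and 1.12 ± 0.530 in Cervical libraries (n = 6). The largest falls were at feature 198952, with a log2 ratio of -2.78 ± 0.35 (edgeR adjusted p = 2.25e-08), and feature 236311, with -2.73 ± 0.35 (adjusted p = 3.48e-08). Feature 198952 had 0.356 ± 0.271 CPM in Thoracic (SD, n = 8) and 2.87 ± 0.539 in Cervical libraries (n = 6). These features are of low abundance, with 30 to 202 counts per segment at the rises and 13 to 123 at the falls. Direction followed abundance. Tested features were divided into 10 bins of equal size by mean abundance. In the highest bin 8182 were higher and 147 lower in Thoracic. In the lowest, 408 were higher and 3304 lower. Counts were also more concentrated in Thoracic libraries, where the top 1% of features took 27.3% against 21.5% in Cervical ones. Such a difference across whole libraries can give calls of this kind. With a smooth (lowess) offset over abundance 38304 features passed. Of these 30081 had also passed without it, 354 with the opposite direction. A difference smooth in abundance therefore does not account for all calls. Among libraries with few low-count barcodes 21043 of 52433 features passed. Without Thoracic libraries 2, 3, 6 and 7, chosen after the clusters had been seen, 30902 passed.

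**Figure D2:**
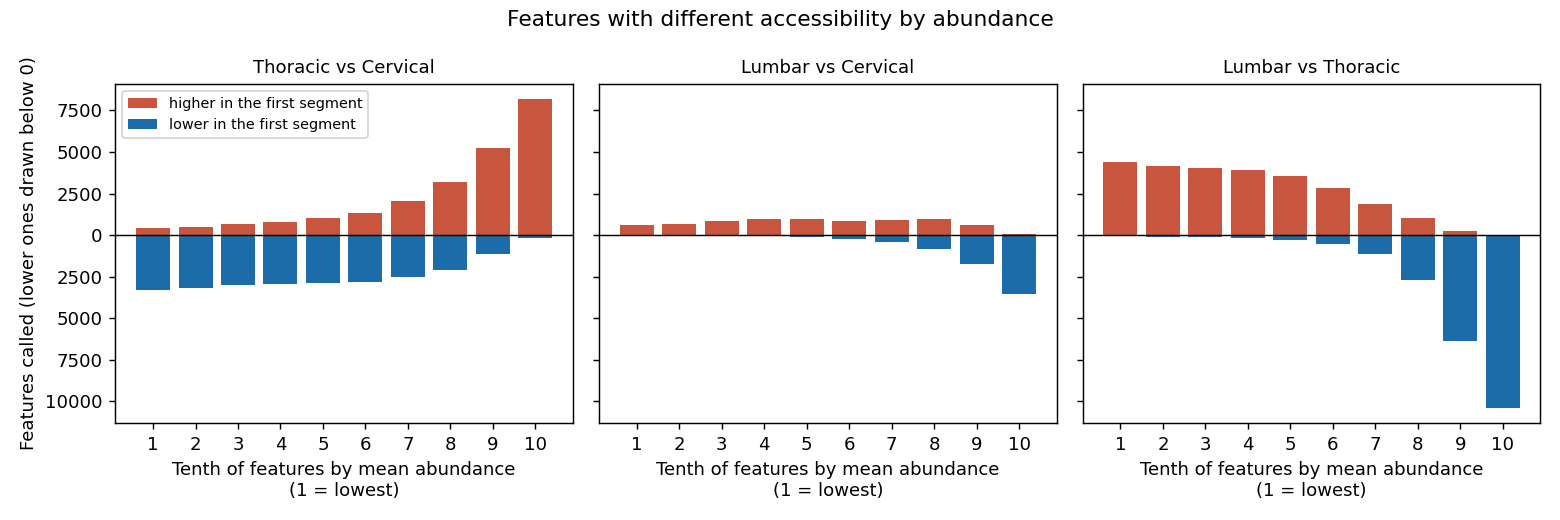
Number of features called (y axis, calls lower in the first segment drawn below 0) in each of 10 bins of tested features by mean abundance (x axis, 1 = lowest), for the 3 comparisons. In the highest bin 8182 features were higher in Thoracic than in Cervical libraries, while 10387 were lower in Lumbar than in Thoracic and 3537 lower in Lumbar than in Cervical libraries.

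Within families, the Thoracic to Cervical difference was found at 15348 of 35014 features tested in family A and at 7258 of 24717 in family B. Pooled over libraries, most Cervical nuclei of family A lay in cluster 1 (61.8%), while the largest group of Thoracic ones lay in cluster 9 (34.4%). In family B these were cluster 3 (59.6%) and cluster 7 (37.2%). Thoracic libraries differed in this. In libraries 2, 3, 6 and 7 cluster 9 held 29.4% to 36.5% of all nuclei and cluster 12 of family B 18.3% to 26.6%. In libraries 1, 4, 5 and 8 cluster 10 of family A held 14.5% to 20.1% and cluster 7 15.9% to 18.3%, while cluster 9 held at most 6.89%. Family E had 1320 called features of 10700, family D 1173 of 21038, family F 98 of 2986 and family C 16 of 335 (edgeR). Families A and B shared 3350 calls of the same direction among 15974 features tested in both, where independent lists would share 1414, and 135 calls of opposite direction. Nuclei of both families came from the same libraries, so the overlap was taken again with each family from other libraries. With A from odd-numbered and B from even-numbered libraries 486 calls were shared and 114 expected. With the libraries exchanged 521 were shared and 120 expected. The expected numbers treat all features alike, although calls and their direction varied with abundance. An overlap above them therefore does not show that the same single features changed in both families. The difference itself differed between families A and B at 1983 of 15974 features (edgeR interaction term). Among libraries with few low-count barcodes, where fewer features reached the count minimum, 7451 features passed in family A, 3840 in B, 569 in E, 113 in D, 1 in F and 1 in C. Without Thoracic libraries 2, 3, 6 and 7 these were 9576 in A, 4382 in B, 792 in E, 418 in D, 35 in F and 21 in C.

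**Figure D3:**
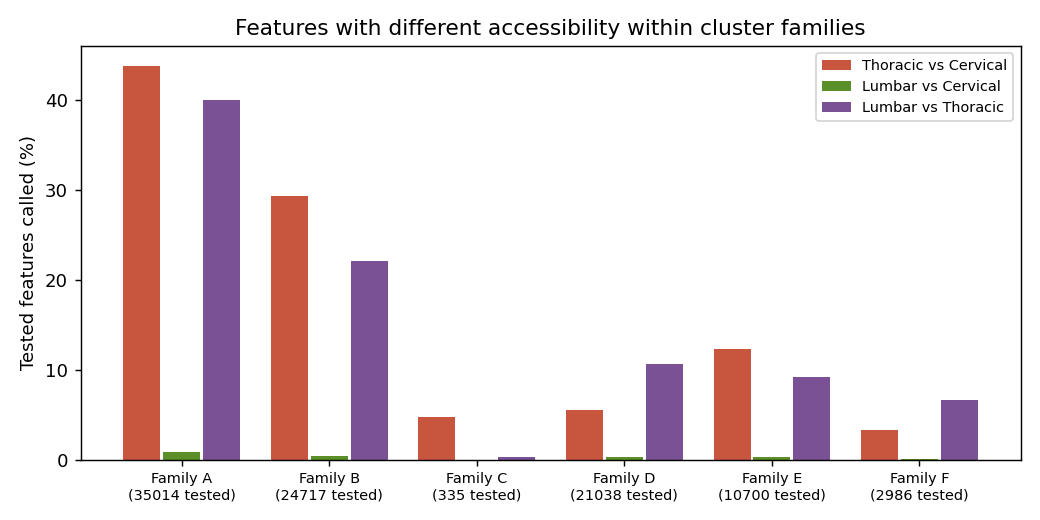
Percent of tested features called in each family (y axis) for the 3 comparisons, with the number tested under each family. In family A 15348 features were called between Thoracic and Cervical, 14017 between Lumbar and Thoracic and 314 between Lumbar and Cervical libraries.

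Lumbar and Cervical nuclei differed in the shares of 5 families. Family D made up 9.68% ± 1.43 (SD, n = 6) of the nuclei of a Lumbar library, against 4.32% ± 0.369 in Cervical libraries (n = 6), a ratio of 2.24. Family C made up 13.6% ± 8.64 against 6.37% ± 0.810, and family F 3.86% ± 0.735 against 2.57% ± 0.419. Lumbar library 2 alone had 31.0% of its nuclei in family C, and the other 5 Lumbar libraries 8.32% to 11.8%, so that without it the difference for C was 3.76 percentage points in place of 7.24. With nuclei of at least 500 counts the difference for C was 16.3 points, and with at least 2000 counts 3.43. Families A (39.4% ± 5.19 against 48.04% ± 1.31) and B (24.6% ± 4.23 against 31.0% ± 1.19) took smaller Lumbar shares. The exact two-sided permutation test gave an adjusted p of 0.0041 for families A, B, C and D and 0.0070 for F (n = 6 and 6), from an unadjusted p of 0.00216 for A to D, the smallest these permutations can give. Families E (6.73% ± 1.03 against 6.35% ± 0.364, adjusted p = 0.52) and G (1.18% ± 0.263 against 1.24% ± 0.233, adjusted p = 0.77) did not pass the exact test. The call for F ended with nuclei of at least 500 counts, where the difference was 0.877 percentage points. Family E passed without Lumbar library 2, with a difference of 0.767.

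Fewer features separated Lumbar from Cervical libraries: 14583 of 110034 passed in edgeR, 7477 higher and 7106 lower in Lumbar. With DESeq2 size factors the split was 6320 higher and 9094 lower, and in DESeq2 itself 5226 and 8505; it was 3975 and 7798 with no minimum of counts, 5297 and 3832 with a smooth offset over abundance and 6369 and 3599 without the deepest nuclei, so neither direction prevailed throughout. At 2-fold or more, 1402 features were higher and 43 lower. The largest rises were at feature 172741, with a log2 ratio of 2.22 ± 0.17 (SE, edgeR adjusted p = 3.50e-12), and feature 302554, with 1.91 ± 0.39 (adjusted p = 0.0012). Feature 172741 had 12.9 ± 1.54 CPM in Lumbar and 2.82 ± 1.15 in Cervical libraries (SD, n = 6 each). The largest falls were at feature 366005, with -1.48 ± 0.16 (edgeR adjusted p = 9.01e-08), and feature 29007, with -1.47 ± 0.29 (adjusted p = 0.00082). In the bin of highest abundance 48 features were higher and 3537 lower in Lumbar. The count was 1722 when each library was reweighted to equal family shares. It was 9129 with the smooth offset and 9471 with the feature rows that hold no count in some libraries included.

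Within families, few features separated Lumbar from Cervical libraries, and most of them were lower in Lumbar. Only features with at least 200 counts within a family were tested, and over all nuclei the most abundant features were mostly lower in Lumbar too. The smooth offset over abundance was not run within families, so whether this direction goes beyond abundance was not tested. Family A had 314 called features of 35014 (54 higher, 260 lower), family B 114 of 24717 (12 and 102), family D 67 of 21038 (16 and 51), family E 36 of 10700 (5 and 31) and family F 2 of 2986 (both lower; edgeR). In family C edgeR called 0 of 335 features, with 20 at an unadjusted p under 0.05; no other tool was run within families. Families A and B shared 53 calls of the same direction, against 1.45 for independent lists, and 0 of opposite direction. The number for independent lists again treats features of all abundances alike. With each family from other libraries, at most 22 features were called in A and 5 in B, so few that the overlap rests on 1 shared call, where 0.00178 was expected, in 1 exchange of libraries; in the other, 0 features were called in B. The difference itself differed between families A and B at 7 of 15974 features in edgeR's interaction test. In family B, 70 features passed among nuclei of at least 2000 counts, and the counts for D, E and F were 40, 18 and 0 without Lumbar library 2.

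Lumbar and Thoracic nuclei differed in families B, C, D and G. Family D made up 9.68% ± 1.43 (SD, n = 6) of Lumbar and 13.3% ± 1.42 (SD, n = 8) of Thoracic nuclei, and family B 24.6% ± 4.23 against 29.6% ± 1.71. Families C (13.6% ± 8.64 against 6.05% ± 1.00) and G (1.18% ± 0.263 against 0.585% ± 0.2502) took larger Lumbar shares. Without Lumbar library 2 the mean for C was 10.1% ± 1.62 (SD, n = 5), and the difference 4.08 percentage points in place of 7.56. In the exact two-sided permutation test the adjusted p was 0.0035 for C, 0.0041 for D and G and 0.0058 for B (n = 6 and 8). Families A, E and F had an adjusted p of 0.95, 0.29 and 0.95 in the same exact test (n = 6 and 8), but their calls and directions varied with the processing. Family A passed as lower in Lumbar with coarser clusters (-10.1 points) and with nuclei of at least 2000 counts (-3.97), and as higher with thinned nuclei (5.75). Family F passed as higher in Lumbar with nuclei of at least 2000 counts (2.35) and as lower without the deepest nuclei (-1.44), and family E as lower with nuclei of at least 500 counts (-1.57) and with thinned nuclei (-2.10). Among libraries with many low-count barcodes family D held 9.68% ± 1.43 (SD, n = 6) of Lumbar and 13.96% ± 1.32 (SD, n = 3) of Thoracic nuclei. With 3 Thoracic libraries the smallest exact permutation p was 0.0238, which families C, D and G reached, and no family passed after adjustment (adjusted p = 0.056 for these 3). With nuclei of at least 2000 counts the difference for D turned to 0.589 percentage points.

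Accessibility differed between Lumbar and Thoracic libraries at 48100 of 110034 features, 26081 higher and 22019 lower in Lumbar (edgeR), with 7812 higher and 2199 lower at 2-fold or more. The balance of directions turned under other scalings, with 21640 higher and 24371 lower under DESeq2 size factors, 19508 and 23519 in DESeq2 itself, 10406 and 11395 with a smooth offset over abundance, and 21307 and 37698 with no minimum of counts. The median log2 ratio of all tested features was 0.17, and 0.02 with that offset, so single ratios are read against this shift. The largest rises were at feature 198952, with a log2 ratio of 2.45 ± 0.36 (SE, edgeR adjusted p = 2.78e-07), and feature 321440, with 2.43 ± 0.33 (adjusted p = 3.91e-08). The largest falls were at feature 406269, with -1.63 ± 0.15 (edgeR adjusted p = 3.15e-11), and feature 3099, with -1.62 ± 0.19 (adjusted p = 1.49e-09). Feature 406269 had 21.7 ± 2.91 CPM in Lumbar (SD, n = 6) and 68.0 ± 23.0 in Thoracic libraries (n = 8). Its log2 ratio was -0.94 with the smooth offset and -1.13 without Thoracic libraries 2, 3, 6 and 7, without which feature 3099 had -1.005. In the bin of highest abundance 16 features were higher and 10387 lower in Lumbar. With the smooth offset 21801 features passed; 16631 of these had also passed without it, 1459 of them with the opposite direction. Among libraries with many low-count barcodes 22144 of 45917 tested features passed.

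Within families, the Lumbar to Thoracic difference was found at 14017 of 35014 features in family A, 5471 of 24717 in B, 2247 of 21038 in D, 988 of 10700 in E, 200 of 2986 in F and 1 of 335 in C (edgeR). The largest group of Lumbar nuclei of family A lay in cluster 2 (50.5%) and of family B in cluster 3 (63.5%). For Thoracic nuclei pooled over libraries these were clusters 9 and 7, which were large in different libraries. Cluster 9 held 29.4% to 36.5% of all nuclei in Thoracic libraries 2, 3, 6 and 7 and 0.328% to 6.89% in the other Thoracic libraries. Cluster 7 held 0.649% to 4.38% in the former and 15.9% to 18.3% in the latter. The difference itself differed between families A and B at 1373 of 15974 features (edgeR interaction term). The calls within family D depended on which Thoracic libraries entered: 101 features passed without Thoracic libraries 2, 3, 6 and 7, and 4228 with Thoracic libraries 2, 3 and 7 only. In the same order, 8424 and 8562 passed in family A, 2147 and 4574 in B, 250 and 478 in E, 58 and 4 in F and 11 and 1 in C.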

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

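The tests of the share of family E, of Thoracic libraries 2, 3, 6 and 7, of overlap between barcodes and of features marking clusters 14 to 17 were chosen after the results had been seen.

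Single libraries stood apart from the rest of their segment in 4 of the 36 groups of values looked at, where chance flags about 1 in 20 groups. In Lumbar library 2 family C held 31.0% of nuclei, against 8.32% to 11.8% in the other 5 Lumbar libraries, and family A held 29.7%, against 39.2% to 44.5%. The median nucleus of Lumbar library 2 had 1707 counts, against 2126.5 to 2323. In Cervical library 3 family C held 4.81% of nuclei, against 6.29% to 6.97% in the other 5 Cervical libraries.

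The difference between segments differed between families A and B, by the interaction test in edgeR, at 1983 features for Thoracic against Cervical, at 7 for Lumbar against Cervical and at 1373 for Lumbar against Thoracic. Barcodes under 1000 counts held 5.99% of the counts of Cervical, 19.4% of Thoracic and 51.7% of Lumbar libraries. No main comparison used them, and only the alternative of at least 500 counts used a part of them.

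Family D took a larger share of Thoracic than of Cervical nuclei, with a ratio of 3.09. A difference in depth per nucleus was predicted to bring the ratio under 1.5 among nuclei of at least 2000 counts, where it was 2.50. That minimum does not make depths equal, so it cannot set depth aside. With every nucleus thinned to 1000 counts the ratio was 3.51 (15.5% against 4.40%), which argues against unequal depth in clustering as its source. Thinning left families F and G without a cluster and 88.3% of nuclei in their family. The thinned family D is therefore not quite the same group. Depth may still bear on which nuclei reached the minimum of counts. A lower share of the largest families raises all others alike, but the ratio for family E was 1.16 ± 0.0980 (SD of library ratios), against 3.09 ± 0.329 for family D. How the tissue was sampled, such as how much of each kind of tissue a piece held, was not recorded in the sources used here and stays open beside a difference between levels of the cord, which was not tested apart from the libraries of 1 donor.

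Thoracic nuclei of families A and B lay in other clusters than Cervical ones, with an overlap over clusters of 0.313 in family A and 0.470 in family B (1 is complete). It also moved with the clustering alone, though less than with thinned nuclei, to 0.543 in A and 0.593 in B at resolution 0.3 and to 0.328 and 0.484 at 1.2; with the empty rows it was 0.241 and 0.636, and clusters made without called features, which were removed for this pattern, gave 0.941 and 1 and decide nothing. With every nucleus thinned to 1000 counts it was 0.654 in A and 0.766 in B, between the limits of 0.8 and 0.5 set beforehand, but thinning also left 3 clusters in A and 2 in B in place of 4 each, so what part depth may have is open. Without Thoracic libraries 2, 3, 6 and 7 the overlap was 0.516 in A and 0.598 in B, again between these limits, and among libraries with few low-count barcodes 0.429 and 0.542. In Thoracic libraries 1, 4, 5 and 8 cluster 10 of family A held 14.5% to 20.1% of all nuclei, against 0.145% to 0.577% in Cervical libraries. Cluster 7 of family B held 15.9% to 18.3%, against 6.23% to 7.09%. These values argue against Thoracic libraries 2, 3, 6 and 7 as the only source of the pattern. Depth, a part of those libraries, the clustering and a difference in chromatin between levels of the cord cannot be told apart here.

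Clusters 14 to 17, with 275 nuclei in all, came to 93.75% or more from Lumbar library 2. Several barcodes of 1 droplet or nucleus counted as separate nuclei are a candidate explanation, since barcodes in these clusters shared rarely seen features with a mean overlap of 0.0385 to 0.0732, against at most 0.00414 in clusters found in 10 or more libraries. A cell type found only in that library could not be tested: at most 1 feature marked any of these clusters at 4-fold with 50 counts, but 70 nuclei drawn from each larger cluster gave 0 such features too.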

How the results depend on the processing

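Chosen after the data had been seen were the smooth offset over abundance, the fits of 2 segments, the left-out libraries, the kinds of file, the empty rows, the clusters without called features and the joining at 0.4 and 0.6. Of 275 values for shares of nuclei under an alternative, 232 kept direction and side of the threshold. Of 84 counts of features over all nuclei, 74 stayed within 1.5 times, as did 48 of 90 within families. The log2 ratios of the named features kept direction and call in the 273 fits in which a feature still reached the minimum of counts. These features were chosen from the same data as called, largest in ratio and with no overlap between libraries of the 2 segments. Their kept direction was therefore largely set by that choice. Only features 172741, 366005, 406269 and 3099 reached the minimum of counts under every alternative run for their comparison, and none of the Thoracic against Cervical features did among libraries with few low-count barcodes. Unless a cause is stated, the cause was not tested. The gene window, the HOX and gene list results and Scrublet were not run, since features have no names, and families F and G had no cluster with thinned nuclei or without called features. The minimum of 200 counts limits what could be tested, with 335 features in family C and 2986 in family F, whose counts are spread over more features than those of the other families.

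Over all nuclei, Thoracic against Cervical gave 74575 features with no minimum of counts, where more features were tested, 28728 with only these 2 segments, 30902 without Thoracic libraries 2, 3, 6 and 7 and 21043 among libraries with few low-count barcodes, where fewer features and libraries entered. With the smooth offset it gave 38304, of which 30081 had also passed without it, 354 with the opposite direction; clusters were not recomputed with that offset. Lumbar against Cervical gave 1722 with equal family shares, 9129 with the smooth offset and 9471 with the empty rows. Lumbar against Thoracic gave 21801 with the smooth offset, 30320 with only these 2 segments and 22144 among libraries with many low-count barcodes. Leaving out each library in turn gave 40079 to 46452 for Thoracic against Cervical, 10125 to 13141 for Lumbar against Cervical and 38371 to 47982 for Lumbar against Thoracic.

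Where a feature still reached the minimum of counts, leaving out each library gave log2 ratios for Thoracic against Cervical of 2.22 to 2.56 at feature 229703, 2.18 to 2.46 at 227589, -3.04 to -2.64 at 198952 and -3.00 to -2.65 at 236311; feature 198952 was not tested without any 1 Cervical library, 236311 without Cervical library 3 or 5, and 227589 without Thoracic library 3. For Lumbar against Cervical they were 2.08 to 2.42 at feature 172741, -1.59 to -1.40 at 366005 and -1.66 to -1.33 at 29007; feature 302554 reached the minimum of counts in only 1 such fit, with 1.72. For Lumbar against Thoracic they were 2.33 to 2.73 at feature 198952, which was not tested without any 1 Lumbar library, 2.31 to 2.66 at 321440, -1.68 to -1.51 at 406269 and -1.71 to -1.46 at 3099.

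No shared deviation of libraries of the same number was found: their correlation was above 0.1 in none of the 18 pairs. This cannot show that such libraries were handled apart. With the library number as a block (replicate block) 42835 features passed for Thoracic against Cervical. For Lumbar against Cervical 13974 passed, and for Lumbar against Thoracic 43576.

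Within families, Thoracic against Cervical gave without Thoracic libraries 2, 3, 6 and 7 9576 in A, 4382 in B, 418 in D, 792 in E and 35 in F; among libraries with few low-count barcodes 7451 in A, 3840 in B, 1 in C, 113 in D, 569 in E and 1 in F; with binarized counts 5 in C, 504 in D and 10 in F; and with nuclei of at least 2000 counts 2 in C and 860 in E. Lumbar against Cervical gave with at least 2000 counts 70 in B, 20 in E and 0 in F, with binarized counts 27 in D, 19 in E and 0 in F, and without Lumbar library 2 40 in D, 18 in E and 0 in F. Lumbar against Thoracic gave without Thoracic libraries 2, 3, 6 and 7 8424 in A, 2147 in B, 11 in C, 101 in D, 250 in E and 58 in F; among libraries with many low-count barcodes 8562 in A, 4228 in D, 478 in E and 4 in F; with at least 2000 counts 3335 in B, 0 in C and 521 in E; with DESeq2 size factors 0 in C; with binarized counts 47 in F; and without Lumbar library 2 2 in C and 118 in F.

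Shares are given as differences in percentage points. Joined at 0.4, families C and F are 1 family (clusters 4 and 11) and D and E are 1 (clusters 5 and 6), and joined at 0.6, B lacks cluster 8, so these values are not for the families as defined above. With other clusters, each cluster went to the family that the largest group of its nuclei belonged to, which left 86.2% to 97.8% of nuclei in their family. For Thoracic against Cervical, resolution 0.3 gave -1.22 for A (call ended) and -7.95 for C (call gained), and resolution 1.2 turned C to 0.560. Nuclei of at least 2000 counts turned B to 1.84, gave C a call at -5.19 and ended those of E (0.897) and F (0.263). C turned to 1.02 with at least 500 counts, 0.779 without called features, and 0.151 without Thoracic libraries 2, 3, 6 and 7, and gained a call at -2.16 with thinned nuclei; C and F together gave 1.02, a call. B without cluster 8 gave 3.04, a call, and E lost its call at 0.818 among libraries with few low-count barcodes. For Lumbar against Cervical, at least 500 counts turned E to -0.185 and ended the call of F (0.877), at least 2000 turned G to 0.202, and E gained a call without Lumbar library 2 (0.767); D and E together gave 5.75, a call.

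For Lumbar against Thoracic, A turned to -10.1 at resolution 0.3 and -3.97 with at least 2000 counts, passing in that direction in both, turned to -2.76 with at least 500, -0.319 with the empty rows and -0.438 among libraries with many low-count barcodes, and gained a call with thinned nuclei (5.75) and without called features (5.28). D turned to 0.589 with at least 2000 counts. E gained a call with at least 500 counts (-1.57), thinned nuclei (-2.10) and without called features (-1.18); D and E together gave -4.26, a call. F turned to 0.0606 at resolution 0.3, 0.856 at 1.2, 2.35 with at least 2000 counts, 0.0335 with at least 500, 0.283 without Thoracic libraries 2, 3, 6 and 7, and 0.117 without Lumbar library 2, passing in that direction at 1.2 and with at least 2000 counts, and gained a call in its own direction without the deepest nuclei (-1.44); C and F together gave 7.51, a call. Among libraries with many low-count barcodes, with 3 Thoracic libraries, calls ended for these families: the differences were -3.81 for B, 8.01 for C, -4.27 for D and 0.829 for G.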

Other observations

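The shares over nuclei outside family C and the unassigned clusters were computed after the results had been seen.

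Family C varied most between Lumbar libraries, so shares were also taken over the nuclei outside it. Family D then made up 14.2% ± 1.44 (SD, n = 8) of Thoracic, 11.4% ± 1.07 (SD, n = 6) of Lumbar and 4.62% ± 0.4002 (SD, n = 6) of Cervical nuclei. Family E made up 7.88% ± 0.5998 of Lumbar and 6.79% ± 0.345 of Cervical nuclei, with an adjusted p of 0.0071 in the exact permutation test (n = 6 and 6). Family A made up 46.1% ± 1.84 of Lumbar and 41.6% ± 1.39 of Thoracic nuclei, with an adjusted p of 0.0024 in the exact permutation test (n = 6 and 8).

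Within families A and B, Thoracic libraries differed from one another. Cluster 9 held 0.871% to 91.7% of the family A nuclei of a Thoracic library and at most 1.58% of a Cervical one. Cluster 12 held 0.680% to 86.7% of the family B nuclei of a Thoracic library and at most 1.06% of a Cervical one. Cluster 18 held 11 nuclei, all of Cervical library 2, whose barcodes shared rarely seen features with a mean overlap of 0.266.

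The libraries were also split in 100 ways into groups of the same sizes, the real split included. Over 10000 features, Thoracic against Cervical gave 4363 calls in the real split and at most 2606 in the others. Lumbar against Cervical gave 1393 and 163, and Lumbar against Thoracic 4377 and 2303. For all 3 only the real split reached the real count, so a chance division of these libraries is an unlikely source. The splits cannot tell a difference between levels of the cord from technical differences between segments, such as the kind of file.

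Within families, over up to 5000 features, the real and the highest other counts for Thoracic against Cervical were 2178 and 1381 in A, 1541 and 653 in B, 16 and 12 in C, 293 and 225 in D, 629 and 157 in E and 98 and 31 in F. Only the real split reached the real count in each. A share of 1 in 100 is the smallest these splits can give, and it was not adjusted over the families and comparisons. For Lumbar against Cervical the counts were 64 and 4 in A, 14 and 0 in B, 27 and 2 in D, and 27 and 3 in E, and only the real split reached the real count in these 4. Chance is left open in F, with 2 and 2, where 3 of 100 splits reached 2 and the number of splits had been raised after a smaller draw was seen. In C, with 0 and 1, the splits decide nothing, since every split reaches a real count of 0. For Lumbar against Thoracic the counts were 1975 and 1074 in A, 1141 and 650 in B, 569 and 399 in D, 492 and 177 in E and 200 and 52 in F, and only the real split reached the real count in these. In C, with 1 and 13, 7 of 100 splits reached 1, and chance cannot be excluded.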
